A study of Homo sapiens with 4 samples.

How the data were processed

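RNA-seq libraries of A673 Ewing sarcoma cells infected with a lentivirus carrying an shRNA against HNRNPK or against GFP were analysed, with 2 libraries per group. Per the labels' protocols, cells were grown in DMEM with 10% serum and selected with puromycin, and total RNA was extracted with TRIzol 5 days after infection and made into libraries with the NuGEN Encore Complete kit. The authors deposited a table of whole-number counts per Ensembl gene and a table of FPKM values for the same genes, and no sample was left out. The submitters' processing notes name STAR 2.3.0, Cufflinks 2.1.1 and the genome build hg19, without saying which step each served. The tool and annotation behind the counts are not given in the sources used here, nor is whether counting used the strand, so genes that overlap, that lie antisense to another gene or that have near-identical copies may share reads. Between 53.7% and 54.5% of counts above 50 were even numbers, and genes with 2 counts outnumbered genes with 1 or 3 in each library, so the unit of counting may in part be the mate and not the fragment; counting intervals would then be too narrow. The deposited FPKM values were used as given. They were made by the authors' own estimate per gene and are not a rescaling of the deposited counts: 83 to 303 genes per library had at least 1000 counts and an FPKM of 0. The FPKM table held 1 line that named no gene, which was left out. The length column of the deposited tables (a value of another kind, not a measurement) was not used. Coordinates are those of the deposited table in hg19, written with a first base of 1.

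Column names showed the group of each library but not the replicate number of the sample titles. Columns were therefore taken as 2 libraries per group with no number, and the replicate numbers were not used to pair them. The names end in a suffix, 75 or 86, shared between the groups. The differences between suffixes in the 2 groups correlated at 0.366 across protein-coding genes, and those between knockdown and control in the 2 suffixes at 0.196. What the suffix stands for is not given in the sources used here. It was used as a block only in alternatives added after the data had been seen, and ratios within suffix are given for HNRNPK, for some other genes and for the lists that camera called.

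Totals ran from 61219529 to 90408702 counts, a 1.48-fold range, and 28953 to 36115 genes had a count. TMM factors were 1.18 for shGFP-75, 0.964 for shGFP-86, 0.944 for shHNRNPK-75 and 0.932 for shHNRNPK-86. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 24857. The main test, fixed before the data were examined, was edgeR 4.0.16 glmQLFit and glmQLFTest on the deposited counts with TMM factors and group as the only term, under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic. Normalised levels are TMM-scaled CPM values (counts scaled to library size), given as mean ± SD of 2 libraries. Reads amplified by PCR without molecular identifiers are not independent molecules. With 2 libraries per group, an exact two-sided permutation test cannot reach a p below 0.333.

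Gene lists, 27 in all, were written before the data were examined. Each was tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01, at least 5 tested members), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way and does not compare them with other genes. Members past the threshold were counted over all genes tested and adjusted over the list alone. Libraries were compared, by correlation and principal components, on protein-coding genes with a mean above 200 counts.

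The rule for named genes took HNRNPK, EWSR1 and FLI1 whatever their values, then the 10 largest rises and falls and the 3 smallest p per direction among named protein-coding or similar genes with an adjusted p under 0.05, a mean of at least 5 CPM and both knockdown libraries beyond both controls, and from each list the 2 members of smallest p with up to 2 more that carry what the list is about. Of these parts, the one that needs an adjusted p under 0.05 gave 0 genes. After the values had been seen, the 10 protein-coding genes of smallest unadjusted p in each direction under the other conditions (2917 eligible) and the members of the cholesterol list past its own adjustment were added. In all, 79 genes were carried through the alternatives. Some genes that this rule takes, and 1 of the gene lists, are not reported here; they stayed in the tests, the adjustments and the counts over lists.

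Alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library size alone), DESeq2 1.42.0, limma-voom, no filter, a mean CPM of at least 5, leaving out each library, the suffix as a block, and the log2 ratio of mean FPKM values with a pseudocount of 0.1, which understates changes of low genes. Limma on log2(FPKM + 1) was added. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

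The scripts were tested on simulated counts with the library sizes of the knockdown and control libraries and each gene's mean over all of them. Among genes with a mean of at least 5 CPM, 100 were changed 2-fold, 100 were changed 8-fold and a further list was lowered 2-fold. The shares recovered therefore speak only for genes at that level. At a low dispersion, over 23935 genes, edgeR recovered 84% of the 2-fold and 100% of the 8-fold changes with 6 false calls. At the dispersion fitted to these libraries, over 22377 genes, it recovered 1% and 69% with 12 false calls, limma-voom recovered 1% and 65% with 11, and DESeq2 recovered 2% and 90% with 135. Camera gave a p of 2.73e-06 for a simulated lowered list at the fitted dispersion, and 1 of 50 unchanged lists had a p under 0.05. Genes were drawn independently and without a suffix difference, so false calls of lists whose genes move together were not checked. The lists that camera called in the real data had estimated correlations of 0.111 to 0.419.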

Results

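RNA-seq was carried out on A673, a cell line established from Ewing sarcoma, a bone and soft-tissue tumour driven by the EWSR1-FLI1 fusion. Cells were infected with a lentivirus carrying a short hairpin RNA (shRNA) against HNRNPK, which encodes the RNA- and DNA-binding protein hnRNP K, or against GFP as the control. RNA was taken 5 days after infection. Each group had 2 libraries, named here by group and by the suffix 75 or 86 that ends their column names: shGFP-75, shGFP-86, shHNRNPK-75 and shHNRNPK-86. The deposited table held 85905364 counts for shGFP-75, 66234733 for shGFP-86, 90408702 for shHNRNPK-75 and 61219529 for shHNRNPK-86 over 55765 genes. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

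Libraries with the same suffix resembled each other more than libraries of the same group did. Across 10897 protein-coding genes, the Pearson correlation of log2 CPM was 0.915 between the 2 libraries of suffix 75 and 0.907 between those of suffix 86, against 0.879 within shGFP and 0.900 within shHNRNPK. These correlations are across genes, which are not independent replicates. The first principal component (47.2% of the variance) separated the suffixes and the second (32.5%) separated knockdown from control. The small cytoplasmic and nuclear RNAs RN7SL1, RN7SL2 and RN7SK took 5.77% of the counts in shGFP-75, 0.842% in shGFP-86, 3.22% in shHNRNPK-75 and 2.16% in shHNRNPK-86. The mitochondrial ribosomal RNA MT-RNR2 took 9.45%, 14.6%, 11.8% and 14.9% in the same order. The 95% Wilson intervals of these shares reached at most 0.00892 percentage points to each side and cover counting error only. What the suffix stands for is not known. Because the libraries split along it, the log2 ratio of knockdown to control within each suffix is given for each gene list that camera called and for some genes.

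The first comparison asked whether the shRNA lowered its target. HNRNPK (ENSG00000165119; hg19 chromosome 9, 86582998 to 86595569, minus strand) had 33591 and 21536 counts in shGFP-75 and shGFP-86, and 11585 and 4957 in shHNRNPK-75 and shHNRNPK-86. The normalised level was 335 ± 4.09 CPM (SD, n = 2) in the control and 111 ± 34.5 CPM (SD, n = 2) in the knockdown, a 3.01-fold difference in the fit. The log2 fold change was -1.59 with a standard error of 0.38, and the ratio within suffix was -1.29 for 75 and -1.96 for 86. Both knockdown libraries thus lay below both control libraries, in the direction the labels state. The processed pseudogenes HNRNPKP4 (log2 fold change -1.98 ± 0.39 SE) and HNRNPKP2 (-2.42 ± 0.55 SE), near-identical copies that may share reads with HNRNPK, also had lower counts in both knockdown libraries and are uncertain as genes of their own. Of the partners of the fusion, EWSR1 (ENSG00000182944; chromosome 22, 29663998 to 29696515) stood at 147 ± 2.75 CPM in control and 157 ± 40.1 CPM in knockdown (SD, n = 2 each). FLI1 (ENSG00000151702; chromosome 11, 128556430 to 128683162) stood at 52.6 ± 35.1 and 41.9 ± 10.9 CPM. The groups overlapped for both, and gene counts do not separate the fusion transcript from the unfused genes. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the unadjusted p of HNRNPK was 0.00617 and it did not pass the threshold over all genes, whereas DESeq2 gave an adjusted p of 0.025, the smallest of its alternatives, which otherwise ran from 0.095 to 1. An exact two-sided permutation test of these 4 libraries cannot go below 0.333.

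**Figure D1:**
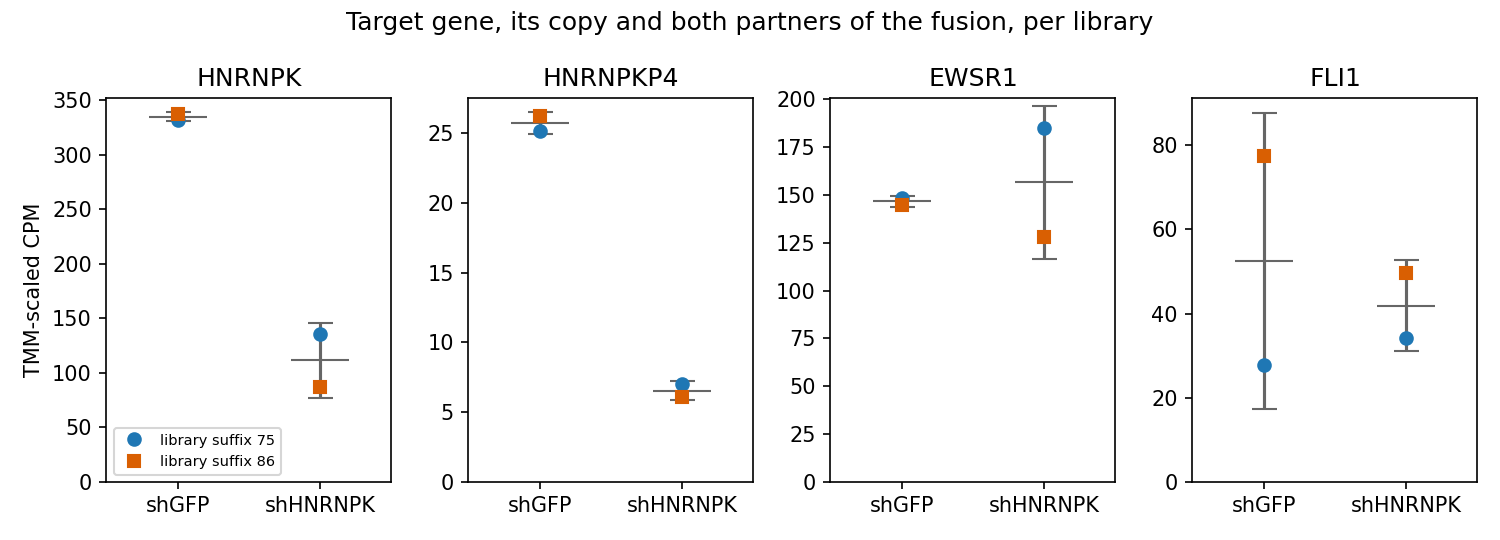
TMM-scaled CPM (linear axes from 0) of HNRNPK, its pseudogene HNRNPKP4, EWSR1 and FLI1 in the 2 shGFP and the 2 shHNRNPK libraries. Points are single libraries by suffix, and horizontal bars with whiskers are group means with SD (n = 2). HNRNPK lay at 332 and 338 CPM in the control libraries and at 136 and 87.0 CPM in the knockdown libraries, while the groups overlapped for EWSR1 and FLI1.

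The second comparison asked which genes differed between knockdown and control across the transcriptome. The genes with the smallest p on the higher side included PIPOX, a peroxisomal oxidase of sarcosine and pipecolic acid, at 1.41 ± 0.131 CPM in control and 20.5 ± 5.11 CPM in knockdown (SD, n = 2 each). BHLHE41, a transcriptional repressor of the circadian clock, stood at 1.09 ± 0.524 CPM in control and 11.9 ± 3.48 CPM in knockdown. The protease inhibitor A2M stood at 2.58 ± 0.304 and 35.0 ± 28.1 CPM, and the collagen VI chain COL6A3 at 1.04 ± 0.799 and 12.2 ± 1.16 CPM. On the lower side were FDFT1, which encodes squalene synthase, at 204 ± 1.89 CPM in control and 59.4 ± 8.97 CPM in knockdown, and PPIB, a prolyl isomerase of the endoplasmic reticulum, at 43.2 ± 4.50 and 11.9 ± 0.582 CPM. None of these genes passed the adjusted threshold. In the authors' FPKM values the groups overlapped for PIPOX, at 2.78 and 0.841 in the control libraries and 3.73 and 1.46 in the knockdown. They also overlapped for BHLHE41, at 0 and 1.20 in control and 0.582 and 0.820 in knockdown. For A2M, COL6A3, FDFT1 and PPIB the groups did not overlap there and kept the direction of the counts. Of 24857 genes tested, 15438 of them protein-coding, edgeR called 0 at an adjusted p under 0.05, and so 0 at a change of at least 2-fold. At an unadjusted p under 0.05 there were 951 genes, 381 higher and 570 lower in the knockdown, where 1243 would be reached by chance, and with the suffix as a block there were 1447. The smallest adjusted p was 0.99997. Both knockdown libraries lay above both control libraries for 14.7% of the genes and below them for 17%, where chance gives 16.7% in each direction. The common dispersion was 0.591, a biological coefficient of variation of 76.9%. Other tools and filters gave other counts: limma-voom called 0, DESeq2 called 150 (56 higher, 94 lower) and edgeR without a filter on low counts called 183 (50 higher, 133 lower). Of the DESeq2 calls, 69 had no count in any library of a group, and 45 had a mean of at least 5 CPM. With the suffix as a block edgeR called 0 genes, and with the block and a mean CPM of at least 5 it called 5, namely PIPOX, ELL2, ANTXRL, GOLGA8G and MROH2B. Without shGFP-86 it called ANTXRL, GOLGA8G, RN7SKP230, RN7SL4P and RN7SL5P, all lower, of which the last 3 are copies of the 7SK and 7SL RNAs and GOLGA8G belongs to a duplicated family, so that their reads are uncertain. The members of these sets of 5 were named after their values were seen.

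The 10 genes of smallest unadjusted p in each direction were chosen after the values were seen, since no gene met the rule fixed before the data were examined. On the higher side, PIPOX (chromosome 17, 27277531 to 27384234) had a log2 fold change of 3.86 ± 0.49 (SE), with 3.47 within suffix 75 and 4.17 within suffix 86. BHLHE41 had 3.44 ± 0.64, A2M 3.76 ± 0.72, COL6A3 3.55 ± 0.75, SIPA1L2 2.48 ± 0.52, CARD16 2.31 ± 0.48 and AKAP8L 1.59 ± 0.37. The other 3 were MBD3L5, MBD3L3 and MBD3L4 at 4.91, 5.43 and 5.38, neighbouring near-identical copies on chromosome 19 whose reads cannot be assigned with certainty. The FPKM table listed MBD3L3 and MBD3L4 at 0 in all 4 libraries. On the lower side, FDFT1 (chromosome 8, 11653082 to 11696818) had -1.78 ± 0.33, with -1.95 within suffix 75 and -1.62 within suffix 86. PPIB (chromosome 15, 64448011 to 64455404) had -1.85 ± 0.35, HMGCS1 -1.72 ± 0.35, the glutathione transferase GSTA4 -2.25 ± 0.44, the diacylglycerol kinase DGKA -2.26 ± 0.45, PPP1R1A -1.80 ± 0.38 and RHOQ -1.82 ± 0.40. ANXA8L1 (-2.06 ± 0.42) and SYT15 (-1.96 ± 0.41) lie in a duplicated part of chromosome 10 and are uncertain. ANTXRL, also on chromosome 10, had 2077 and 190 counts in the control and 0 in both knockdown libraries, with an FPKM of 0 in all 4. In the authors' FPKM values GSTA4, ANXA8L1 and SYT15 had higher group means in the knockdown, against the direction of the counts. Each of these means was carried by 1 library, and the other knockdown library lay below both controls.

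The third comparison set 27 gene lists, fixed before the data were examined, against all other genes. Camera called the cholesterol synthesis list lower in the knockdown at the preset correlation of 0.01 (adjusted p = 8.9e-05), and the call was lost with an estimated correlation (adjusted p = 0.857) and by fry (0.909). Both of these tests take their degrees of freedom from the 4 libraries and can rarely pass an adjustment over 27 lists. A call lost there therefore leaves a list undecided. Of its members, 20 of 24 measured had negative log2 fold changes, 17 were lower within both suffixes and 0 were higher within both. The median was -1.0, with -1.03 within suffix 75 and -0.81 within suffix 86. Squalene synthase FDFT1 and HMG-CoA synthase HMGCS1 stood at 59.4 and 18.5 CPM in knockdown, 3.43-fold and 3.30-fold below their control levels of 204 and 60.9 CPM. Over all genes tested 0 members passed edgeR's threshold, and 5 did when adjusted over the list alone: FDFT1, HMGCS1, the lanosterol demethylase CYP51A1 (-1.63 ± 0.37 SE), the sterol-responsive transcription factor SREBF2 (-1.95 ± 0.48) and the sterol oxidase MSMO1 (-1.24 ± 0.33). Camera's call of this list held without each library in turn, with adjusted p from 0.000733 to 0.0334. In the FPKM values the median log2 ratio of group means over the list was -0.93, with 18 of 24 members negative, as in the counts. By pair, the list's median gap to all genes was -1.47 within suffix 75 and 0.41 within suffix 86, so the direction did not hold in both pairs there. SREBF2 had a higher group mean FPKM in the knockdown, carried by shHNRNPK-86 (8.74, against 0.813 in shHNRNPK-75 and 4.99 and 1.74 in the controls). The groups also overlapped for HMGCS1, at 15.7 and 1.45 in shGFP-75 and shGFP-86 and 4.56 and 2.41 in shHNRNPK-75 and shHNRNPK-86. FDFT1, CYP51A1 and MSMO1 had lower FPKM values in both knockdown libraries than in both controls.

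**Figure D2:**
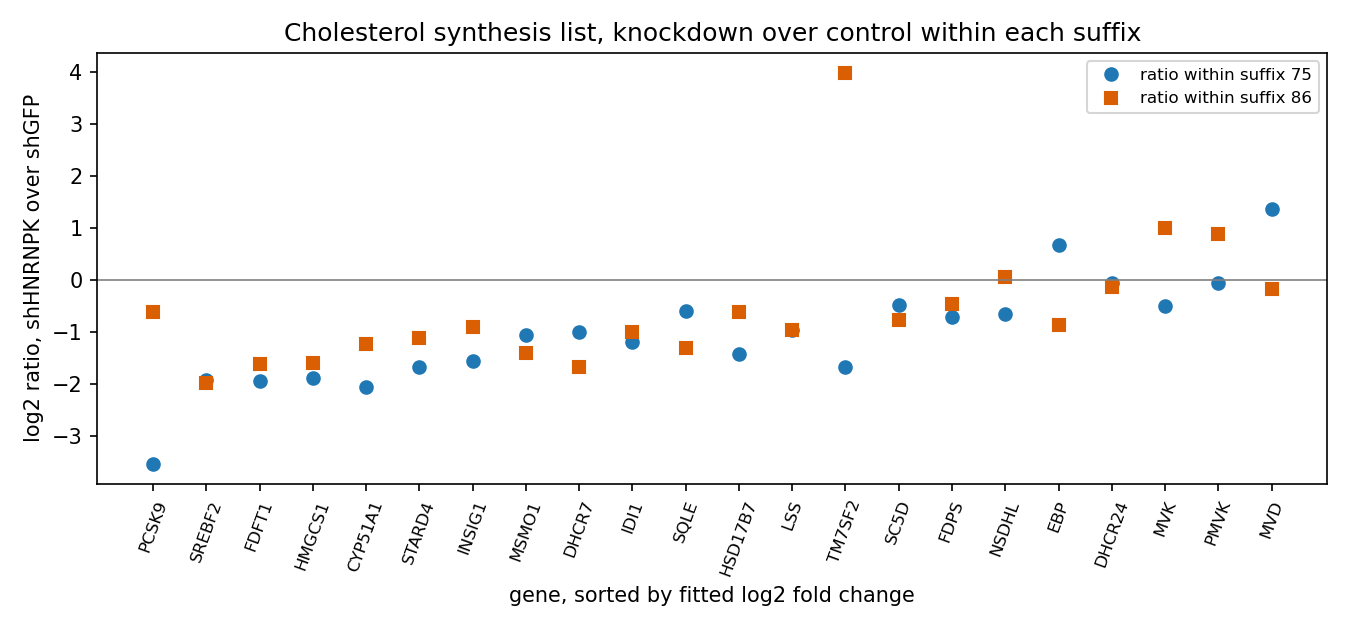
Log2 ratio of knockdown to control (vertical axis) for 22 of the 24 measured members of the cholesterol synthesis list, sorted by fitted log2 fold change, with 1 point per gene and library suffix. Of these members 16 lay below 0 within both suffixes and 0 lay above 0 within both.

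Camera called the list of NF-kB targets and cytokines higher in the knockdown (adjusted p = 7.5e-05), and the call was lost with an estimated correlation (adjusted p = 0.857), by fry (0.909) and without shHNRNPK-75 (0.0586). Of 22 measured NF-kB targets and cytokines, 20 had positive log2 fold changes and 14 were higher within both suffixes, with a median of 0.94 (0.94 within suffix 75, 0.99 within suffix 86). The cytokine genes IL1B and IL8 went from 84 and 22 and from 110 and 30 counts in the control to 443 and 360 and to 1071 and 184 counts in the knockdown, at log2 fold changes of 3.28 ± 0.78 and 3.33 ± 0.93 (SE). TNFAIP3, a feedback inhibitor of NF-kB, stood at 2.41 ± 0.68, and IL6 had 0 and 11 counts in control against 72 and 201 in knockdown. Over all genes, and adjusted over the list alone, 0 members passed. At a mean of at least 5 CPM only 8 members were measured, and IL1B and IL8 stood at 0.587 and 0.779 CPM in control. In the FPKM values the list's median log2 ratio was 0.43, with 16 members positive and 6 negative. IL6 and TNFAIP3 were higher there in both knockdown libraries. The groups overlapped for IL1B (2.33 and 0 in control, 3.71 and 0 in knockdown) and IL8 (0.396 and 0.231, against 2.69 and 0.237).

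Camera called the list of genes reported to be lowered by EWSR1-FLI1 higher in the knockdown and did not call the list of those reported to be raised by it; the lists were not tested against each other. The call (adjusted p = 7.5e-05) was lost with an estimated correlation (adjusted p = 0.857), by fry (0.909) and without shHNRNPK-75 (0.152). Of 25 genes lowered by the fusion, 22 had positive log2 fold changes and 19 were higher within both suffixes, with a median of 0.97 (0.78 within suffix 75, 0.65 within suffix 86). The cell-cycle inhibitor CDKN1A had 72 and 58 counts in control and 397 and 262 in knockdown (2.51 ± 0.70 SE), and IGFBP5 stood at 1.76 ± 0.61 and the TGF-beta receptor gene TGFBR2 at 1.01 ± 0.42. Over all genes, and adjusted over the list alone, 0 members of this list passed. Of the 34 genes raised by the fusion, 17 had positive and 17 negative values, with a median of -0.01 and a camera adjusted p of 0.961. PPP1R1A (-1.80 ± 0.38) and STEAP2 (-1.05 ± 0.33) were lower in both knockdown libraries, the nuclear receptor gene NR0B1 (1.45 ± 0.51) was higher in both, and NKX2-2 stood at -0.14 ± 0.47. In the FPKM values the mean of CDKN1A was lower in the knockdown, where shGFP-86 alone carried the control mean (15.03, against 0.604 in shGFP-75 and 0 and 1.45 in the knockdown), and the median of the lowered list was 0.

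Camera also called higher the lists of ATF4 and amino acid response, of unfolded protein response chaperones and of immediate-early genes (adjusted p = 0.0164, 0.0289 and 0.000576), and the 3 calls were lost with an estimated correlation (0.912, 0.857 and 0.857) and each without some libraries. Of 30 ATF4 and amino acid response genes, 21 had positive values and 15 were higher within both suffixes, with a median of 0.52 (0.64 within suffix 75, 0.26 within suffix 86). DDIT3, a transcription factor of the stress response, stood at 1.40 ± 0.39 (SE), and the amino acid transporter genes SLC3A2 and SLC7A11 at 1.16 ± 0.37 and 1.15 ± 0.38. Of 22 unfolded protein response chaperone genes, 19 had positive values and 13 were higher within both suffixes, with a median of 0.33, but 0.56 within suffix 75 against 0.04 within suffix 86, among them HERPUD1 (0.84 ± 0.42) and the chaperone gene HSPA5 (0.74 ± 0.40). Of 25 immediate-early and AP-1 genes, 21 had positive values and 13 were higher within both suffixes, with a median of 0.50, but 0.21 within suffix 75 against 1.42 within suffix 86; DUSP5 stood at 1.44 ± 0.49 and FOSL2 at 2.92 ± 1.0. The calls of the ATF4 and chaperone lists were lost without shGFP-75 (adjusted p = 0.388 and 0.239) and without shHNRNPK-75 (0.75 and 0.656), and that of the immediate-early list without shGFP-86 (0.490) and without shHNRNPK-75 (0.152). Adjusted over the list alone, 0 members of the 3 lists passed.

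Camera also called higher the lists of ribosomal protein genes, of genes of the mitochondrial genome and of extracellular matrix genes (adjusted p = 0.000349, 0.0235 and 0.0235), and the 3 calls were lost with an estimated correlation (0.857, 0.886 and 0.912). Of 52 cytosolic ribosomal protein genes, 43 had positive values and 36 were higher within both suffixes, with a median of 0.44 (0.41 within suffix 75, 0.50 within suffix 86). RPL24 stood at 315 ± 8.75 CPM in control and 689 ± 54.4 CPM in knockdown, and RPL6 at 394 ± 22.7 and 893 ± 360 CPM (SD, n = 2 each). Of 13 mitochondrially encoded genes, 11 had positive values and 9 were higher within both suffixes, with a median of 0.42 (0.77 within suffix 75, 0.24 within suffix 86); MT-ND2 stood at 1.27 ± 0.54 and MT-ND1 at 0.89 ± 0.43 (SE). Of 33 extracellular matrix and mesenchymal genes, 21 had positive values, 14 were higher and 6 lower within both suffixes, with a median of 0.14 (0.24 within suffix 75, 0.37 within suffix 86); COL6A3, the metalloproteinase inhibitor TIMP1 (1.34 ± 0.34) and fibronectin FN1 (0.40 ± 0.46) were higher in both knockdown libraries. Without shHNRNPK-75 all 3 calls were lost (adjusted p = 0.159, 0.159 and 0.617). The mitochondrial call was also lost without shGFP-75 (0.513) and without shHNRNPK-86 (0.0606), and that of the matrix list without shGFP-86 (0.490). Adjusted over the list alone, 0 members passed. In the FPKM values the median of the ribosomal list was 0.02 and that of the mitochondrial list was -0.24, against the direction of the counts.

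In all, camera called 9 of the 27 lists, 8 higher and 1 lower, while 0 were called with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.909. With 4 libraries these last 2 tests could rarely make a call, so they do not decide. Some of the higher lists share members, for example IL6, listed both as an NF-kB target and as lowered by EWSR1-FLI1. Their calls are thus not independent. Without shHNRNPK-75 camera called 1 list, cholesterol synthesis. Lists outside the 9 also gained a call, autophagy and lysosome without shHNRNPK-86 (adjusted p = 0.0319) and endothelial and muscle markers without shGFP-86 (0.028). The split of the 4 libraries by suffix alone gave 6 camera calls, among them ribosomal proteins, immediate-early genes, extracellular matrix genes and genes lowered by EWSR1-FLI1, and cholesterol synthesis was not called there (adjusted p = 0.385). The crossed split, shGFP-75 and shHNRNPK-86 against the other 2 libraries, gave 1 call, the ATF4 and amino acid response list.

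The lists that camera did not call included those of cell division and RNA processing. The hnRNP family had a median of -0.07 over 30 members and a camera adjusted p of 0.993, with TAF15 at -0.60 ± 0.36 and HNRNPA1 at -0.50 ± 0.36 (SE). The SR splicing factors had -0.03 over 20 members (adjusted p = 0.888), with the splicing kinase genes CLK4 at 0.93 ± 0.41 and CLK2 at 0.62 ± 0.34. The G1/S and DNA replication list had -0.09 (0.888), with POLE2 at -1.11 ± 0.36 and PCNA at 0.43 ± 0.37. The G2/M and mitosis list had 0.03 (0.951), with TPX2 at -0.93 ± 0.34 and TOP2A at -0.96 ± 0.36. Replication-dependent histones had -0.24 (0.888), with HIST1H2AB at -1.17 ± 0.77 and HIST1H3G at -1.42 ± 0.97. Interferon-stimulated genes had -0.13 (0.923), with OAS1 at -1.45 ± 0.49 and ISG20 at 2.89 ± 1.0.

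The remaining lists covered metabolism, cell death and other cell types. Glycolysis and hypoxia genes had a median of -0.08 (camera adjusted p = 0.923), with SLC2A3 at 1.63 ± 0.54 (SE) and ENO2 at -0.80 ± 0.33. The nuclear-encoded respiratory chain had -0.09 (0.785), with NDUFA4 at -0.86 ± 0.51 and ATP5O at -0.84 ± 0.59. Autophagy and lysosome genes had 0.13 (0.213), with CTSL at 1.28 ± 0.47 and BECN1 at 0.98 ± 0.42. The BCL2 family and cell death list had 0.01 (0.785), with HRK at 2 and 0 counts in control and 100 and 9 in knockdown, and MCL1 at 0.66 ± 0.34. Neuronal genes had -0.30 (0.888), with SYT1 at 1.08 ± 0.33 and TUBB3 at -1.70 ± 0.58. Genes tied to hnRNP K in earlier work had 0.15 (0.189), with ALOX15 at 17 and 0 counts in control and 29 and 149 in knockdown. Abundant nuclear and structural noncoding RNAs had 0.23 (0.189), with RNU1-1 at 1.47 ± 0.77 and SNHG1 at 0.56 ± 0.37. Of the marker lists of other cell types, 8 of 18 epithelial, 13 of 18 blood cell and 7 of 16 endothelial and muscle markers had enough counts to be tested, with medians of 0.13, -0.75 and 0.57 and camera adjusted p of 0.888, 0.923 and 0.177. The epithelial splicing factor ESRP2 had 66 and 128 counts in control and 0 in both knockdown libraries and passed when adjusted over its list alone, and CLDN7 stood at -1.87 ± 1.07. CD4 stood at -2.26 ± 0.99, and KDR and MYH3 at 3.03 ± 1.98 and 1.74 ± 0.64.

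**Figure D3:**
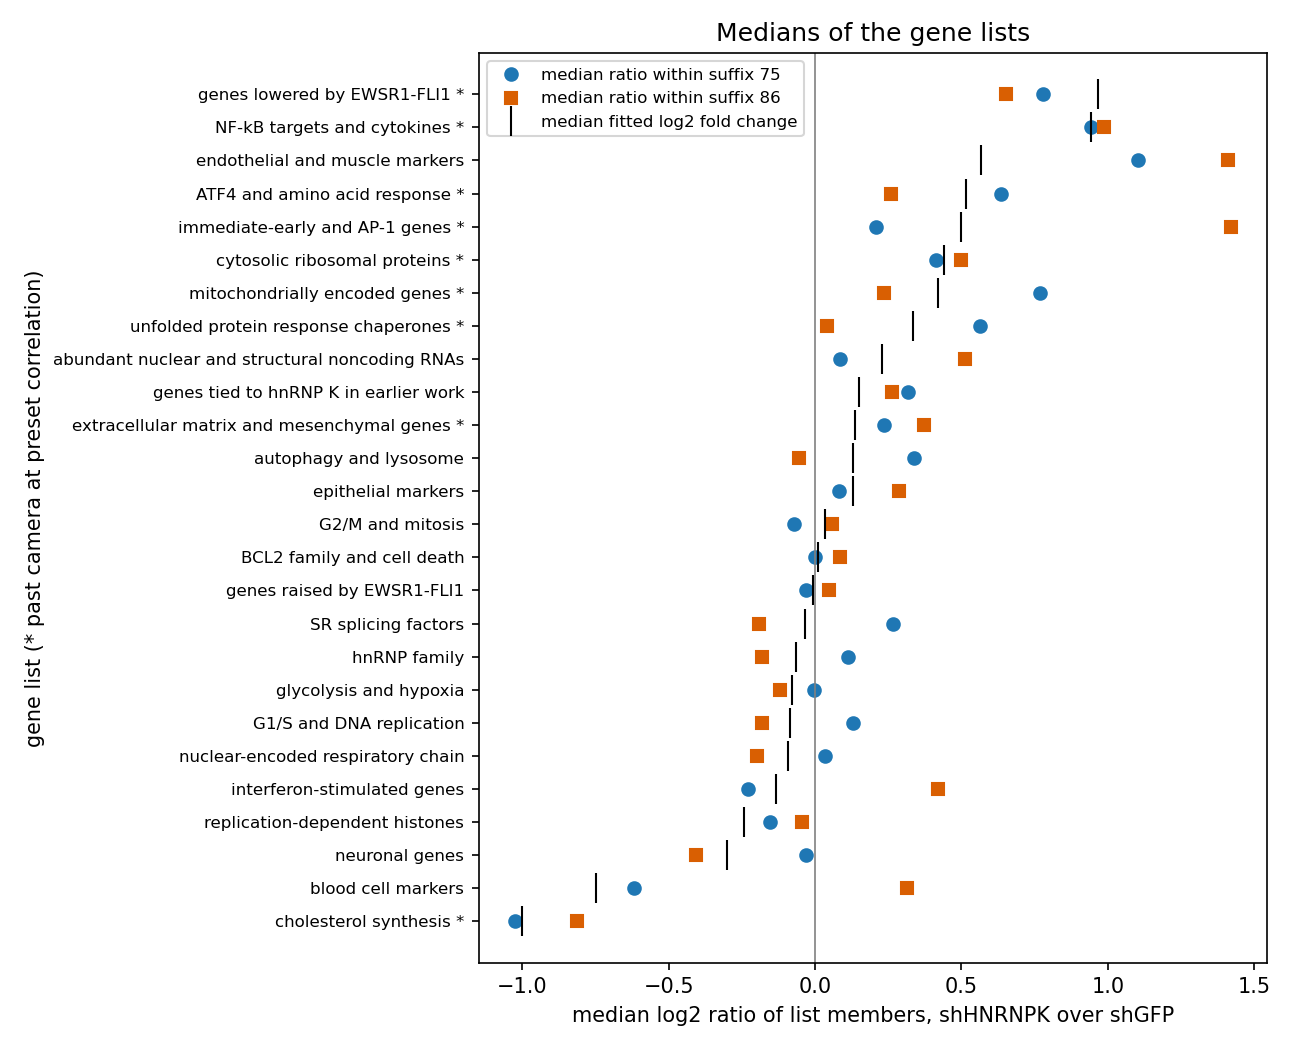
Median log2 ratio of knockdown to control (horizontal axis) of the measured members of each of 26 of the 27 gene lists (vertical axis), within suffix 75, within suffix 86 and as the median of the fitted log2 fold changes. A star marks the 9 lists that camera called at the preset correlation, none of which was called with an estimated correlation. Cholesterol synthesis had the lowest fitted median, -1.0.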

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

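The settings with the suffix as a block, the FPKM fit by limma, the FPKM medians of the lists and the lists at a mean CPM of at least 5 were chosen after seeing the data. No paired analysis was possible on the replicate numbers because the columns carry none; with the replicate block on the column suffix instead, edgeR called 0 genes, HNRNPK stood at -1.62 and 9 lists were called. The count of 0 changed genes, with or without a 2-fold minimum, also held under DESeq2 size factors, upper-quartile factors, library size alone (which moved the median of all genes to -0.21), limma-voom, a mean CPM of at least 5 and limma on FPKM values. It moved to 150 with the DESeq2 Wald test, 183 with no filter, 5 with the replicate block on the suffix and a mean CPM of at least 5, and ran from 0 to 5 leaving out 1 library, with 5 called without shGFP-86; each of these calls was at least 2-fold. Of the 183 calls with no filter, 76 had a group at 0 counts and 83 were among the DESeq2 calls. In simulated counts at the fitted dispersion DESeq2 made 135 false calls, and the cause of its calls here was not tested. Where 1 library is left alone in its group, it is assumed to vary like the other group.

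HNRNPK kept its direction in every setting run, from -1.29 to -1.93 leaving out 1 library and -1.45 in FPKM values, and passed the threshold with DESeq2 alone (-1.57, adjusted p = 0.025). The number of lists called went from 9 to 0 with an estimated correlation and 0 by fry, and ran from 1 to 9 leaving out 1 library, with 1 without shHNRNPK-75. Of the 9 called lists, the median of the mitochondrial list reversed to -0.24 in FPKM values. Among lists not called, medians reversed there from 0.15 to -0.71 for genes tied to hnRNP K, 0.13 to -0.60 for autophagy and lysosome, 0.03 to -0.08 for G2/M and mitosis and -0.75 to 0.67 for blood cell markers. Of the other named genes, 26 passed with DESeq2, 17 with no filter and 1 without shGFP-86.

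Signs turned in the authors' FPKM values for GSTA4 (0.79), ANXA8L1 (0.98), SYT15 (0.99), ESRP2 (0.089), SREBF2 (0.49), CDKN1A (-3.27), SLC3A2 (-0.26), DUSP5 (-0.055), ISG20 (-2.09), IGFBP5 (-0.58), HRK (-1.99), CTSL (-1.17), ENO2 (0.42), CD4 (0.89), MT-ND1 (-0.30), CLK2 (-0.25), NKX2-2 (2.19) and EWSR1 (-0.28). With library size only, EWSR1 stood at -0.10. Leaving out 1 library, CLDN7 ran from -2.85 to 0.35, NDUFA4 from -1.40 to 0.013, HIST1H3G from -2.28 to 0.49, FLI1 from -0.88 to 0.60, EWSR1 from -0.18 to 0.35 and NKX2-2 from -0.31 to 0.044. The cause was not tested for any of these. MBD3L3, MBD3L4 and ANTXRL were listed at an FPKM of 0 in all 4 libraries and gave no FPKM ratio. Genes under 5 CPM and those with a group at 0 are the least certain at this depth and spread.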

Other observations

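Among the 45 genes that DESeq2 called at a mean of at least 5 CPM were several outside the gene lists and outside the genes named so far, listed here after their values were seen. The neuronal splicing factor NOVA1 was higher in the knockdown (log2 fold change 1.98 ± 0.56 SE, adjusted p = 0.04995), as was the zinc-finger gene HIVEP2 (1.79 ± 0.49, 0.0428). The iron-regulating gene HFE (-2.46 ± 0.63, 0.020), the mono-ADP-ribosyltransferase gene PARP10 (-3.03 ± 0.74, 0.011), the corepressor gene TLE2 (-2.65 ± 0.71, 0.0328) and MLLT11 (-1.62 ± 0.42, 0.0214) were lower, as was ACAT2 (-1.34 ± 0.38, 0.04995), a thiolase that makes acetoacetyl-CoA, the substrate of HMGCS1. Of the 45, the main edgeR fit called 0, and edgeR without a filter on low counts called 27, among them NOVA1, HFE, PARP10 and TLE2 but not HIVEP2, MLLT11 or ACAT2. Splitting the same 4 libraries by suffix gave 1104 DESeq2 calls and 0 calls in the main edgeR fit, several times the 150 of the knockdown, which points to a structure of the libraries along the suffix, and the crossed split gave 93 and 0.

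For the patterns weighed here, the tests of the genes at 0 counts, the test of noise shared by the cholesterol list, the test of swapped columns and the count of abundant genes listed at an FPKM of 0 were chosen only after the result was seen.

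The first pattern is the lower cholesterol synthesis list in the knockdown. Scaling between libraries moves the list and all other genes alike, so a scale factor cannot make the gap between their medians. That gap was -0.978 or further from 0 under 4 scalings, but would be near that value whatever the factor, so the scalings were no test. The list is lower only relative to other genes, and whether its level fell in absolute terms cannot be told. Noise between libraries cannot be told apart. Within each suffix, 0% of 10000 random lists matched on mean expression had a median as low as the list's -1.03 and -0.81, but random lists lack the noise that the genes of one list share. With their correlation estimated (0.122) camera gave a p of 0.129, and fry gave 0.0698, so shared noise stays open. By the rule set before the data were examined, the result went with the authors' read counting as a cause. That rule asked for an FPKM gap of 0 or above in at least 1 suffix pair, and the gap was 0.41 within suffix 86. It was -1.47 within suffix 75, and the median of the ratios of group means was -0.93, with 18 of 24 members negative. This cause therefore stays open. A response of sterol genes to the loss of hnRNP K was not tested apart from these explanations and stays open.

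The second pattern is a set of 32 genes, 28 of them protein-coding, with 0 counts in both knockdown libraries and at least 50 in both controls, such as FBN3 (422 and 541 counts in control) and STAB1 (339 and 487). Dropout and a loss of the transcripts in the knockdown cannot be told apart. Dropout may produce sets of this size, as 50 genes were at 0 in shGFP-86 and shHNRNPK-86 with at least 50 counts in the other 2, and 34 in shGFP-86 and shHNRNPK-75, but both pairs include shGFP-86, which had the fewest genes with a count. The remaining pairs gave fewer, with 7 for both controls, 13 for both libraries of suffix 75 and 5 for shGFP-75 and shHNRNPK-86. As for a loss, 10 of the 32 had an FPKM above 0 in both controls, and 2 of these had 0 in both knockdown libraries. Of the 32, 13 had an FPKM of 0 in all 4 libraries and 14 had an FPKM above 0 in a knockdown library. The FPKM values do not decide, since each library also had at least 2603 genes with 0 counts and an FPKM above 1. STAB1 had FPKM values of 3.22 and 0.943 in the knockdown.

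The third pattern is that fold changes from the counts and from the FPKM values disagree. Swapped columns between the tables are argued against, since 4 of the 4 FPKM columns correlated best with the count column of their own name. Across genes, the fold changes correlated at 0.49 (95% interval 0.456 to 0.516, taking genes as independent) in the 2486 genes with the most counts. They correlated at 0.054 in the 2486 genes with the fewest. The genes with the most counts had totals of at least 20287, and 2.65% of them had an FPKM of 0. With an FPKM above 0 in all libraries, their correlation was 0.524. The disagreement thus reached genes with many counts, but the correlation was higher there than in genes with few. Counting noise of low genes is not decided by this test. The interval reached past the limit, set before the data were examined, under which such noise would have been argued against. For genes with fewer counts it cannot be told apart from other causes. Each library had at least 83 genes with 1000 counts or more and an FPKM of 0. These were picked for their high counts, so their number was no test of such noise. No biological explanation was tested for this pattern, and a difference in how the tables assign reads to genes stays open.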
